A study of Xenopus laevis and Petromyzon marinus with 21 samples.

How the data were processed

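Messenger RNA was measured in cultured animal pole explants (animal caps), the pluripotent ectoderm of the blastula, of the frog Xenopus laevis and of the sea lamprey. Per the labels, frog embryos received mRNA for the Wnt ligand wnt8a and the BMP antagonist chordin at the 2-cell stage, which turns caps toward neural crest (induced caps), or were left uninjected and formed epidermis (control caps). Caps of 6 groups, control and induced at stages 9, 13 and 17, were collected with 3 libraries each, 18 in all; lamprey caps were collected at stage 11, with 3 libraries and no treatment. Libraries were prepared from poly(A) RNA with a directional kit, per the labels. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2, aligned with STAR 2.6.0 and counted per gene with HTSeq 1.99.2; the genome builds, annotations and strand setting are not given in the sources used here.

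The deposited values are raw read counts per gene, one column per library, and were used as such after the 5 summary lines of HTSeq (no feature, ambiguous and the like) were set aside. The frog table holds 49282 genes, of which 25573 end in L or S, the copies of a gene on the long and short chromosomes; copies were treated as separate genes, and gene numbers below count copies. Reads that match several places were not counted, so values of near-identical copies, such as those of chrd and nodal3, are uncertain. Control libraries at stages 9, 13 and 17 and induced libraries are named by the letters a, b and c of their columns, which are in no label.

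Frog libraries held 15596247 to 23292078 gene counts (median 19021702), at which a gene at 10 CPM (counts scaled to the library's total, times its TMM factor in frog libraries and without it in lamprey) collects more than 100 counts, and 26736 to 29097 genes were detected. Reads in no gene made up 10.2 to 12.8%, ambiguous reads 0.2 to 0.51% and reads without a unique place 10.3 to 12.2%. Spread between libraries of a group exceeded counting error 19.5 to 67.3 times (chi-square per degree of freedom), and the median coefficient of variation of genes was 14.3 to 22.1% by group. The p-values below therefore measure spread between these samples, which may be technical, since the labels name no separate clutches; intervals and floors of fold changes cover counting error alone.

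Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (TMM scaling, filterByExpr by group, robust dispersion, two-sided) on all 18 frog libraries together, which left 24499 genes. TMM factors ran from 0.785 to 1.4. Adjusted p-values are Benjamini-Hochberg values and 0.05 was the threshold. The 7 pairwise comparisons set induced against control caps at each stage, and induced and control caps of stages 13 and 17 against control caps of stage 9, the blastula; interaction terms tested whether the induction effect changed from stage 9 to 13 and from 13 to 17. Log2 fold changes are given with standard errors (SE), CPM values as mean and SD of 3 libraries. Each SE was derived from the fold change and the test's F statistic, so with empty or nearly empty groups it is only nominal. Where a list in 1 library is set against its sister libraries, ± is the SE over the list's genes. It does not measure spread between libraries, and genes are not replicates. Against a group with no counts, a fold is a lower bound computed with 3 counts over the group; against 1 to 3 counts, the ratio is given with its 95% counting interval. Relative to scaling by library totals, TMM moved the median log2 fold change of all genes; totals minus TMM was −0.06, 0.08 and 0.22 for induced against control caps at stages 9, 13 and 17, −0.71 and −0.50 for induced and −0.79 and −0.73 for control caps of stages 13 and 17 against the blastula, and 0.14 and 0.15 for the interactions.

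Lists of genes were written from general knowledge before the data were examined, 18 in all: pluripotency regulators, regulators shared by blastula and neural crest, neural plate border, neural crest, epidermis, multiciliated cells, ionocytes, goblet and small secretory cells, neural plate, placodes, cement and hatching gland, mesoderm, endoderm, BMP targets, Wnt targets, Hox genes, maternal transcripts and housekeeping genes. Lists overlap (the shared regulators also belong to the crest or border list). Members were counted as higher, lower or not passed at the genome-wide adjusted p, and the counts adjusted over the list alone are given beside. Each list was also tested against all other genes with camera of limma 3.58.1 on log2 CPM (prior 2) with a preset correlation of 0.01, and with a correlation estimated from the data; these p-values were adjusted over the 18 lists of a comparison and are called list adjusted p below.

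Sets of blastula genes and epidermal genes were taken from control caps of stages 17 or 13 against stage 9, at adjusted p under 0.05 and a log2 difference of at least 2, and tested in induced against control caps at the other stage, so that set and test shared no library. Genes were named by rules fixed before the data were examined: per pairwise comparison the 6 of largest change in each direction with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between groups (10% by chance for 3 against 3); per list the members of smallest adjusted p, up to 4 for stages 13 and 17 and 2 elsewhere; the injected genes, pou5f3, sox2, sox3, ventx, klf and shared regulators everywhere; and 5 in each direction per interaction. Members named because 5 or fewer of a list rose or fell were chosen after their values were seen. Results on some genes that these rules pick are not reported here.

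Whether libraries of the same letter belong together was checked from residual correlations: same-letter pairs of different groups, 45 in all, correlated at 0.179 to 0.828, the highest pair of different letters at −0.021, and 18 of 18 libraries matched best with their own letter. Letters were therefore used as a block in an alternative, whose value (called blocked below) is given where it changed a call. The p-values and counts below otherwise come from the fit without the block, which leaves spread shared by letter in the error. Alternatives also covered DESeq2 1.42.0 (its size factors and its Wald test), scaling by library totals, no count filter or a stricter filter of 1 CPM, an adjusted p of 0.01, a 2-fold minimum, copies summed, fits of the compared groups alone, leaving out each library, and leaving out libraries that stood apart. The method was tested on a simulated stage 13 comparison, with the depths and the spread estimated from all 18 frog libraries. Of 100 genes shifted 2-fold 34% were recovered, of 100 shifted 4-fold 75%, and 2.68% of the calls were false. Simulated libraries shared no spread by letter, and far fewer genes were shifted than were called at stage 13. These shares therefore need not hold for the data.

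Lamprey counts were summarised without a test. The lamprey table names 19781 gene models by identifiers that could not be paired with symbols (0 paired), so the planned comparison of gene names between species was not run. Sequences and the splicing of transcripts were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.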

Results

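Frog animal caps injected with wnt8a and chordin mRNA held more neural plate border and neural crest transcripts and less of many epidermal ones than uninjected caps. The difference unfolded over the 3 stages collected. No group received either mRNA alone or another mRNA, so effects of each factor and of injection itself cannot be told apart. Induced and control caps of stages 9, 13 and 17 were compared with 3 libraries per group, and caps of stage 9 served as the blastula. Differential expression was tested with edgeR's quasi-likelihood test, and lists of genes with camera.

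The injected transcripts themselves marked every induced library. The injected Wnt ligand gene wnt8a.L was counted 22664, 12162 and 8070 times in the induced libraries of stage 9. At stage 13 the counts were 511, 1168 and 1832, and at stage 17 145, 221 and 422. Its mean went from 576 ± 263 CPM at stage 9 to 69 ± 35.1 at stage 13 and 12.8 ± 5.08 at stage 17. Control caps held 0.0732, 0.132 and 0.308 CPM at these stages. The log2 fold changes were 12.88, 8.95 and 5.38 (adjusted p = 3.1e-08, 8.1e-08 and 1.6e-06), and the gene was higher in 3 of 3 libraries at each stage. The chordin gene chrd.1.S, which codes for a BMP antagonist, stood at 2560 ± 345 CPM in induced caps of stage 9 (log2 fold change 12.81 ± 0.34, adjusted p = 5.4e-11). It remained at 1270 ± 278 CPM at stage 13 (at least 18800-fold higher) and at 185 ± 37.4 CPM at stage 17 (ratio 9310, interval 1670 to 368000). The copies chrd.1.L and chrd.2.L were lower, with 291 ± 109 and 133 ± 44.5 CPM at stage 9, and reads of the injected sequence may be among them. Counts of chrd.1.L in induced libraries were 4449, 8304 and 7946 at stage 9 and 22, 32 and 33 at stage 13. Those of chrd.2.L were 2131, 4004 and 3409, then 6, 26 and 27, while chrd.1.S still had 23704, 21046 and 17583 at stage 13. A fixed share of stray chrd.1.S reads would not fall so, which argues against it as the main source of both copies' counts at stage 9. Whether these counts came from the embryo's own genes was not tested. Injected and endogenous transcripts cannot be told apart in gene counts, so none of these values is taken as a measure of the embryo's own wnt8a or chordin.

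**Figure D1:**
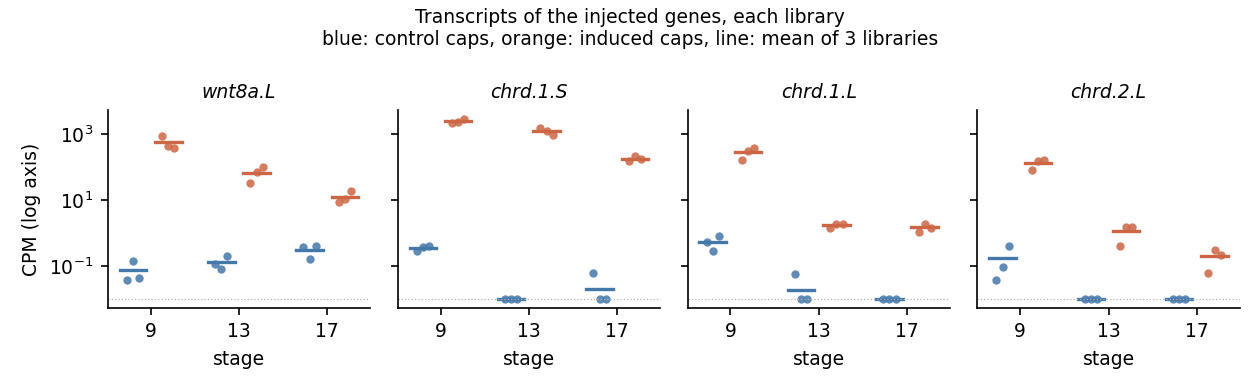
CPM (log axis) of wnt8a.L and 3 chordin genes against stage, each point a library, blue control caps and orange induced caps, lines the means of 3 libraries. Values below 0.01 are drawn at 0.01 (dotted line); the injected transcripts were present in each induced library and declined with stage.

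Stage and treatment both ordered the libraries. The first principal component held 58.7% of the variance and parted the blastula from later stages. The second held 19.5% and parted induced from control caps at stages 13 and 17. As epidermis formed, few genes came to dominate the control libraries. Their 10 most abundant genes took 2.91 ± 0.5% of counts at stage 9, 9.95 ± 0.72% at stage 13 and 13.6 ± 1.5% at stage 17. In induced caps these shares were 3.21 ± 0.33%, 7.05 ± 0.45% and 7.95 ± 0.97%.

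**Figure D2:**
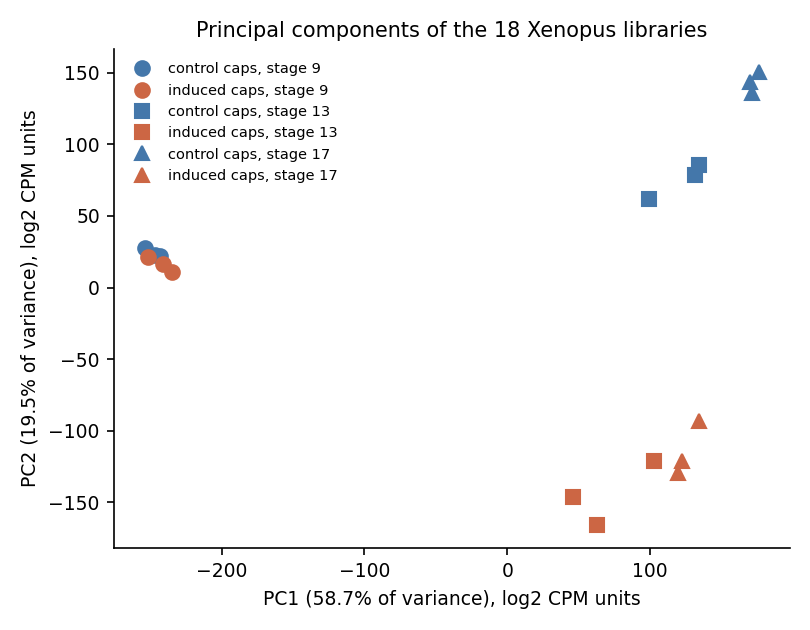
First against second principal component of log2 CPM for the 18 frog libraries, each point a library, blue control caps and orange induced caps, shapes the stages. Libraries of stage 9 lie together, while control and induced caps of stages 13 and 17 lie apart.

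At stage 9, induced caps had already switched on early targets of canonical Wnt signalling and lost part of their BMP response. A nodal-related gene of the dorsal blastula, nodal3.1.L, was at least 3410-fold higher (143 ± 78.5 CPM against no counts). Its relative nodal3.2.L was 4210-fold higher (interval 755 to 166000, adjusted p = 0.00017). The Wnt-regulated zinc-finger factor sp5.L rose by 6.99 ± 0.76 on the log2 scale (adjusted p = 0.00022). The trunk patterning gene hoxd1.S was 426-fold higher (interval 76.1 to 16900, adjusted p = 0.0019). Among dorsal genes, nog.L, which codes for the BMP antagonist noggin, rose by 4.47 ± 0.61 (adjusted p = 0.0017) and the midline factor foxa4.L by 4.73 ± 0.63 (adjusted p = 0.0054). The BMP target id3.L, an inhibitor of differentiation, changed by −3.76 ± 0.47 (adjusted p = 0.00074, 8.02 ± 5.75 against 109 ± 44.8 CPM). The AP-2 factor tfap2a.L of early ectoderm changed by −1.45 ± 0.20 (adjusted p = 0.0017). Each of these genes kept its call when any single library was left out and with the block over all libraries. Fits of the stage 9 libraries alone called fewer of them. Without the block nodal3.1.L (adjusted p = 0.067), sp5.L (0.067), hoxd1.S (0.16), nog.L (0.46), foxa4.L (0.067), id3.L (0.31) and tfap2a.L (0.18) lost the call. With it nog.L (0.18), foxa4.L (0.14), id3.L (0.065) and tfap2a.L (0.19) did. In contrast, the homeobox gene sia1.L (at least 286-fold higher, adjusted p = 0.031) kept it only without induced library a (adjusted p 0.078 to 0.11 without any other). It also lost the call by DESeq2 (adjusted p = 0.66) and with the stage 9 libraries alone without the block (0.25).

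Across the genome 85 genes were higher and 16 lower at stage 9, of 24499 tested. A fit of the stage 9 libraries alone called 10 higher and 0 lower, and with the replicate block 387 higher and 242 lower. The counts also depended on single libraries: without control libraries a, b or c 41, 42 and 50 genes were higher, without induced libraries a, b or c 158, 47 and 44. Without control libraries b or c 9 and 8 genes were lower, and without induced libraries a, b or c 26, 7 and 8.

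By lists, Wnt targets rose and BMP targets and regulators shared by blastula and neural crest fell at stage 9. Of 46 Wnt targets 8 rose, 0 fell and 38 did not pass. Wnt targets gave 16 and 0 adjusted over the list alone (list adjusted p = 2.2e-26). Of 43 BMP targets the homeobox gene msx2.S rose, 7 fell and 35 did not pass. BMP targets gave 1 and 13 adjusted over the list alone (list adjusted p = 1.3e-21). Of 14 shared regulators 4 fell, both copies of id3 and of tfap2a, while 0 rose and 10 did not pass. Shared regulators gave 1 and 4 adjusted over the list alone (list adjusted p = 7.1e-06). The call of tfap2a.S (−1.02, adjusted p = 0.04) was lost without any library but induced library a (0.073 to 0.24).

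Further lists passed at stage 9 on few genes and with fragile calls. Of 51 epidermal genes dlx3.S, dlx5.S and both copies of tfap2a fell, 0 rose and 47 did not pass. Epidermal genes gave 0 and 4 adjusted over the list alone (list adjusted p = 0.015, adjusted p = 0.37 with an estimated correlation). The mean and median of this list were above 0, opposite in sign to the test. Its list adjusted p was 0.21, 0.063 and 0.46 without control library b, control library c or induced library a. The call of dlx5.S was lost without any library but induced library a (0.072 to 0.28), that of dlx3.S without induced library c (0.055), and that of tfap2a.S as above. Of 43 mesodermal genes the organiser factor gsc.S and nog.L rose, 0 fell and 41 did not pass. Mesodermal genes gave 3 and 0 adjusted over the list alone (list adjusted p = 0.034, 0.088 blocked, adjusted p = 0.61 with an estimated correlation). This call was lost without control library a (0.17), control library b (0.47), induced library a (0.18) or induced library c (0.95). The rise of gsc.S was lost without control library c (0.083) or induced library c (0.054). Of 29 Hox genes both copies of hoxd1 rose, 0 fell and 27 did not pass. Hox genes gave 4 and 0 adjusted over the list alone (list adjusted p = 0.048, 0.082 blocked, adjusted p = 0.75 with an estimated correlation). Their call was lost without control libraries a (0.26), b (0.36) or c (0.14) and without induced libraries a (0.32), b (0.086) or c (0.25). The rise of hoxd1.L was lost without control libraries b (0.06) or c (0.051).

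Lists of border, crest, pluripotency and endodermal genes did not pass at stage 9, with border genes called in both directions. Of 25 border genes 3 rose (among them msx2.S), 3 fell (msx1.L and both copies of tfap2a) and 19 did not pass. Border genes gave 8 and 4 adjusted over the list alone (list adjusted p = 0.46). Of 49 crest genes the metalloprotease gene adam33.L rose, both copies of id3 fell and 46 did not pass. Crest genes gave 3 and 2 adjusted over the list alone (list adjusted p = 0.42). Of 46 pluripotency regulators 2 rose, 0 fell and 44 did not pass. Pluripotency regulators gave 8 and 9 adjusted over the list alone (list adjusted p = 0.089, 0.0065 without control library a and 0.0031 without induced library c). Among those not passed were the POU factor pou5f3.3.L (−0.23, adjusted p = 1) and the SoxB1 factor sox3.S (−0.04, adjusted p = 1). The Kruppel-like factor klf2.L (−2.36, adjusted p = 0.072) passed when blocked (−2.41, 0.041). Of 23 endodermal genes both copies of foxa4 rose, 0 fell and 21 did not pass. Endodermal genes gave 2 and 0 adjusted over the list alone (list adjusted p = 0.11, 0.037 with library totals). The rise of foxa4.S was lost without any library but induced library a (0.08 to 0.18).

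Genes of differentiated ectoderm were not called at stage 9. With edgeR's test no member rose or fell among 36 genes of multiciliated cells, 22 of ionocytes, 13 of goblet and secretory cells, 49 of the neural plate and 23 of placodes. The list adjusted p-values were 0.38, 0.87, 0.46, 0.46 and 0.96. Without induced library b they were 0.043 for multiciliated cells, 0.022 for goblet cells and 0.024 for the neural plate. Of all 24499 genes 815 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. This fit left spread shared by letter in the error, and residuals of same-letter control and induced libraries of stage 9 correlated at 0.798 to 0.828. The number therefore cannot tell whether changes lie below the threshold. DESeq2 called 156 higher and 32 lower. Adjusted over the list alone, 1 neural plate gene and 1 placode gene rose. Mean, median and test of the border, multiciliated, ionocyte, goblet, neural plate, placode and endoderm lists differed in sign.

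By stage 13 induced caps expressed the factors of the neural plate border and early neural crest at high levels. The paired-box border specifier pax3.L was at least 8790-fold higher (589 ± 49.2 CPM against no counts). The zinc-finger border specifier zic2.L rose by 11.13 ± 0.46 (adjusted p = 4.1e-10, 214 ± 59.8 against 0.087 CPM). Crest factors of the snail family followed. The gene snai1.L rose by 8.25 ± 0.38 (adjusted p = 1.4e-09, 326 ± 17.8 against 1.09 ± 0.434 CPM) and snai2.L by 6.61 ± 0.39 (adjusted p = 1.2e-08, 425 ± 108 against 4.35 ± 1.95 CPM). A forkhead factor of crest progenitors, foxd3.L, rose by 8.91 ± 0.55 (adjusted p = 8.7e-08) and the SoxE factor sox8.L by 3.97 ± 0.27 (adjusted p = 5.1e-08). Further genes without a count in control caps were sp5.S (at least 1450-fold higher), the anterior ectodermal gene xa-1.L (at least 1480-fold), zic4.S (at least 885-fold) and the membrane protein gene tmem221.S (at least 781-fold). Among the genes of largest decrease were the potassium channel gene kcnh3.L (−6.91), aacs.L, which codes for an acetoacetate-activating enzyme (−6.50), and the T-box factor tbx20.L (−5.94). The fall of irg1.L (−8.05) was lost without control library c (adjusted p = 0.23).

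At this stage 4641 genes were higher and 5236 lower, of which 2711 and 4133 changed at least 2-fold. With library totals the split was 5211 and 4889, so that 51.6% of calls were higher instead of 47%. Of 25 border genes 23 rose, 0 fell, and pax7.S and hes1.L did not pass. Border genes gave 23 and 0 adjusted over the list alone (list adjusted p = 8.2e-18). Of 49 crest genes 37 rose, such as the AP-2 factor tfap2e.S (7.85 ± 0.41, adjusted p = 4.2e-09), 3 fell and 9 did not pass. Crest genes gave 37 and 3 adjusted over the list alone (list adjusted p = 1.6e-13), and stood higher in induced library c than in its sister libraries (0.47 ± 0.12, log2). Those that fell were ets1.L (−2.03 ± 0.20, adjusted p = 1.3e-06), an ETS factor of migrating crest, its copy ets1.S and the semaphorin gene sema3f.L. Of 14 shared regulators 8 rose, both copies of ets1 fell and 4 did not pass. Shared regulators gave 8 and 2 adjusted over the list alone (list adjusted p = 0.0019, adjusted p = 0.063 with an estimated correlation). The fall of ets1.S was lost without control library b (−0.98, adjusted p = 0.073) or induced library a (−0.84, adjusted p = 0.081). Those that rose included the growth regulator myc.L (1.72 ± 0.24, adjusted p = 2.9e-05, 272 ± 80 against 82.4 ± 17.2 CPM) and tfap2a.L (1.03 ± 0.20, adjusted p = 0.00058). The BMP target id3.L did not pass (0.30, adjusted p = 0.63).

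**Figure D3:**
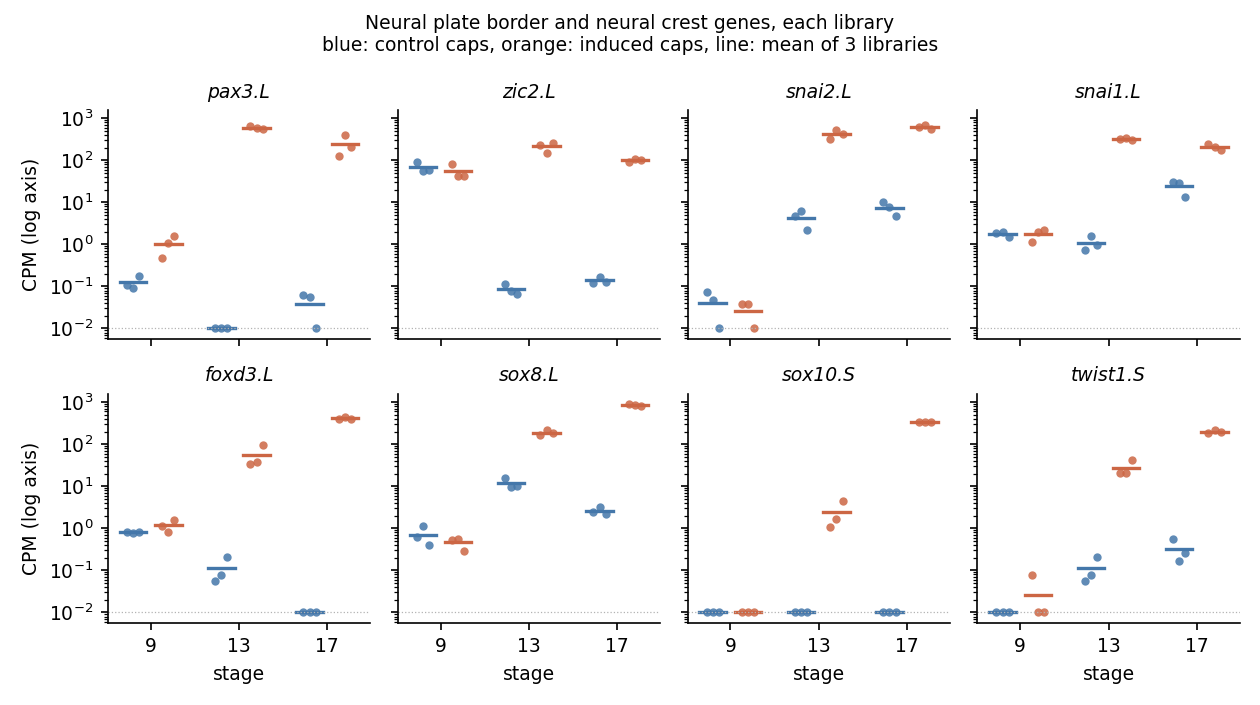
CPM (log axis) of 8 border and crest genes against stage, each point a library, blue control caps and orange induced caps, lines the means of 3 libraries. Values below 0.01 are drawn at 0.01 (dotted line); border genes and snail genes were high in induced caps at stage 13, and sox10.S and twist1.S at stage 17.

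Most genes of epidermis and of its specialised cell types were lower in induced than control caps at stage 13. Against the blastula, 45 of the 51 epidermal genes rose in these induced caps, so they gained less rather than lost. Of 51 epidermal genes 10 rose, 32 fell and 9 did not pass. Epidermal genes gave 11 and 33 adjusted over the list alone (list adjusted p = 9.1e-05, adjusted p = 0.1 with an estimated correlation). The keratin gene krt8.2.L fell by 4.27 on the log2 scale (SE 0.46, adjusted p = 3.2e-06) and the BMP ligand gene bmp7.1.L by 4.15 (SE 0.42, adjusted p = 1.7e-06). In the opposite direction, the keratin gene krt18.1.S rose by 3.91 ± 0.44 (adjusted p = 5.3e-06). Of 36 multiciliated cell genes 0 rose, 33 fell and gmnc.S, tekt2.L and dnah5.L did not pass. Multiciliated genes gave 0 and 34 adjusted over the list alone (list adjusted p = 2.4e-14, adjusted p = 0.1 with an estimated correlation). The dynein gene dnali1.S (−3.02 ± 0.29, adjusted p = 9.6e-07) and the ciliogenic factor rfx2.S (−2.79 ± 0.27, adjusted p = 1.3e-06) were among them. Of 22 ionocyte genes 0 rose, 17 fell, such as the grainyhead-like factor tfcp2l1.S (−3.67 ± 0.41, adjusted p = 4.2e-06), and 5 did not pass. Ionocyte genes gave 0 and 19 adjusted over the list alone (list adjusted p = 9.8e-08, adjusted p = 0.1 with an estimated correlation). Of 13 goblet and secretory genes the intelectin gene itln1.S rose, 9 fell and 3 did not pass. Goblet genes gave 1 and 9 adjusted over the list alone (list adjusted p = 0.004, adjusted p = 0.21 with an estimated correlation). The keratin gene krt7.S stood at 3880 ± 352 against 17300 ± 1080 CPM (−2.15 ± 0.35, adjusted p = 0.00014). Induced library c held more of these transcripts than its sister libraries, by 2.25 ± 0.32 for ciliated cells, 2.04 ± 0.49 for ionocytes, 1.46 ± 0.41 for goblet cells and 0.67 ± 0.20 for the epidermal list (log2; median −0.01 for the last).

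Signalling targets and regional genes also differed between induced and control caps at stage 13. Of 46 Wnt targets 31 rose, 0 fell and 15 did not pass. Wnt targets gave 31 and 0 adjusted over the list alone (list adjusted p = 2.8e-12). The feedback inhibitor axin2.S rose by 5.0 ± 0.42 (adjusted p = 3e-07, a mean of 671 against 21.1 CPM) and the Wnt effector tcf7.S by 4.96 ± 0.26 (adjusted p = 4.2e-09). Of 43 BMP targets 6 rose, 26 fell, among them the pseudoreceptor gene bambi.L (−3.67 ± 0.29, adjusted p = 2e-07), and 11 did not pass. BMP targets gave 6 and 28 adjusted over the list alone (list adjusted p = 9.9e-06, adjusted p = 0.1 with an estimated correlation). Of 49 neural plate genes 24 rose, 7 fell and 18 did not pass. Neural genes gave 24 and 7 adjusted over the list alone (list adjusted p = 0.00021, adjusted p = 0.21 with an estimated correlation). The SoxC factor sox11.L (4.52 ± 0.23, adjusted p = 2.8e-09) and the adhesion gene ncam1.S (4.28 ± 0.30, adjusted p = 7.7e-08) were among those that rose. Induced library c held more neural plate transcripts (0.87 ± 0.15, log2) and BMP target transcripts (0.84 ± 0.31) than its sister libraries.

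Posterior and dorsal genes rose alongside. Of 29 Hox genes 16 rose, hoxa11.S fell and 12 did not pass. Hox genes gave 16 and 2 adjusted over the list alone (list adjusted p = 6.2e-06, adjusted p = 0.21 with an estimated correlation). The hindbrain gene hoxb1.L was 1460-fold higher (interval 261 to 57500) and hoxb2.S at least 331-fold. Of 43 mesodermal and organiser genes 20 rose, among them nog.L (7.96 ± 0.75, adjusted p = 9.7e-07), 6 fell and 17 did not pass. Mesodermal genes gave 22 and 6 adjusted over the list alone (list adjusted p = 0.00065, adjusted p = 0.22 with an estimated correlation). Induced library b carried more mesodermal (1.12 ± 0.30 on the log2 scale) and Hox transcripts (1.37 ± 0.22) than its sister libraries. Without it and induced library c of stage 17 the list adjusted p-values were 0.0015 for mesoderm and 4.1e-05 for Hox genes.

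Genes of the naive blastula did not move together at stage 13. Of 46 pluripotency regulators 15 rose, 16 fell and 15 did not pass. Pluripotency regulators gave 18 and 18 adjusted over the list alone (list adjusted p = 0.96). The Oct4 homologue pou5f3.2.L was lower in induced caps (−2.0 ± 0.48, adjusted p = 0.0033), as was the homeobox gene ventx2.1.S (−2.42 ± 0.30, adjusted p = 1.3e-05). The Kruppel-like factors klf2.S (−6.20 ± 0.54, adjusted p = 4.5e-07) and klf5.L (−2.22 ± 0.18, adjusted p = 2.3e-07) fell, while klf17.L rose (1.53, adjusted p = 0.0017). Some members passed only when blocked. These were pou5f3.2.S (0.99, adjusted p = 0.053, against 0.88 and 0.045 blocked), ventx1.1.L (−1.48, adjusted p = 0.051, against −1.45 and 0.04) and ventx1.2.L (−2.11, adjusted p = 0.06, against −1.93 and 0.02). For pou5f3.2.S libraries a, b and c held 86.2, 21 and 27.2 CPM in induced and 22.9, 16.7 and 27.8 CPM in control caps. Its rise thus came mainly from library a.

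At stage 17 induced caps expressed genes of specified and migrating neural crest. The crest progenitor factor foxd3.L was at least 6940-fold higher (417 ± 23.4 CPM). The SoxE factor sox10.S of crest lineages was at least 5690-fold higher (342 ± 4.6 CPM against no counts). The receptor gene pdgfra.S, which marks crest and mesenchyme, was at least 3700-fold higher. The gene xa-1.L was at least 6280-fold higher, but uneven between libraries (64.3, 767 and 267 CPM). The retinoic acid hydroxylase gene cyp26c1.L was 31500-fold higher (interval 5660 to 1250000). The gene sox8.L rose by 8.35 ± 0.33 (adjusted p = 2.3e-10, 849 ± 47.6 against 2.59 ± 0.567 CPM) and snai2.L by 6.38 ± 0.38 (adjusted p = 8.5e-09). For snai1.L the effect was 3.08 ± 0.29 (adjusted p = 6.5e-07, 208 ± 28.8 against 24.7 ± 9.57 CPM). In the other direction, the phospholipase gene plcb2.L was at least 1040-fold lower. The opsin genes val.L (−12.68 ± 1.75, adjusted p = 2.8e-05) and tmtops.L (at least 582-fold lower) were nearly absent. The BMP feedback gene szl.L fell by 11.24 on the log2 scale (SE 1.89, adjusted p = 0.00017). The carbonic anhydrase gene ca7.S was at least 252-fold lower, and the transporter gene slc6a3.S fell by 10.68 (SE 1.58, adjusted p = 9e-05).

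In all, 5427 genes were higher and 5586 lower at stage 17 (3384 and 4224 at least 2-fold). With library totals the split was 7078 and 4423, so that 61.5% of calls were higher instead of 49.3%. Of 49 crest genes 36 rose, the endothelin receptor gene ednra.L fell and 12 did not pass. Crest genes gave 38 and 1 adjusted over the list alone (list adjusted p = 1.8e-17). Of 14 shared regulators 10 rose, 0 fell and id3.L, id3.S, ets1.L and sox5.S did not pass. Shared regulators gave 10 and 0 adjusted over the list alone (list adjusted p = 1.2e-05). The ETS factor ets1.S, lower at stage 13, was now higher (3.66 ± 0.39, adjusted p = 2.3e-06), and myc.L rose by 2.11 ± 0.24 (adjusted p = 3.9e-06). Of 25 border genes 17 rose, such as zic2.L (9.43 ± 0.43, adjusted p = 9.9e-10) and zic1.L (8.70 ± 0.52, adjusted p = 8.4e-09), pax7.S and hes1.L fell and 6 did not pass. Border genes gave 17 and 2 adjusted over the list alone (list adjusted p = 3.5e-07, adjusted p = 0.057 with an estimated correlation).

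**Figure D4:**
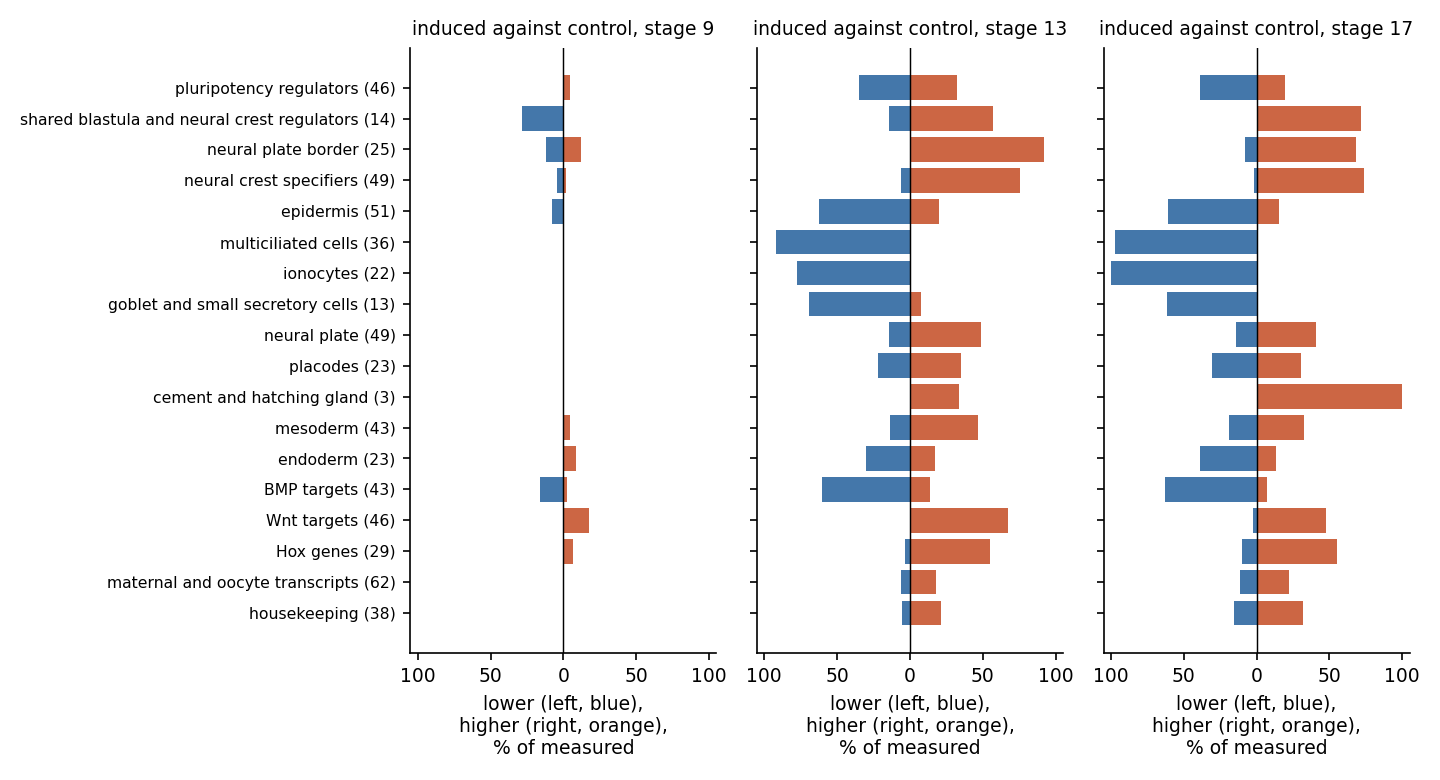
Share of the measured genes of each list (percent) that were higher (right, orange) or lower (left, blue) in induced than control caps at stages 9, 13 and 17, with the number of genes measured in brackets. Border and crest genes rose and genes of epidermal cell types fell at stages 13 and 17, while few genes had changed at stage 9.

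Many transcripts of epidermal cell types were lower in induced than control caps at stage 17. All 22 ionocyte genes fell and 0 rose. Ionocyte genes gave 0 and 22 adjusted over the list alone (list adjusted p = 8.4e-11, adjusted p = 0.057 with an estimated correlation). The proton pump gene atp6v1c2.L (−7.39 ± 0.67, adjusted p = 4.6e-07) and the anion exchanger gene slc4a9.L (−6.94 ± 0.68, adjusted p = 9.9e-07) were examples. Of 36 multiciliated cell genes 0 rose, 35 fell and gmnc.S did not pass. Multiciliated genes gave 0 and 35 adjusted over the list alone (list adjusted p = 3.6e-17, adjusted p = 0.078 with an estimated correlation). The axonemal genes dnali1.S (−5.57 ± 0.32, adjusted p = 7e-09) and spag6.S (−6.71 ± 0.52, adjusted p = 1.1e-07) were among those that fell. Of 51 epidermal genes 8 rose, 31 fell and 12 did not pass. Epidermal genes gave 8 and 31 adjusted over the list alone (list adjusted p = 0.00057, adjusted p = 0.12 with an estimated correlation). The keratin gene krt19.L stood at 30.4 ± 9.66 against 1160 ± 87.9 CPM (−5.26 ± 0.58, adjusted p = 3e-06), while krt18.1.S rose by 4.69 ± 0.46 (adjusted p = 1.1e-06). Of 13 goblet and secretory genes 0 rose, 8 fell, among them the pioneer factor foxa1.L (−7.33 ± 1.14, adjusted p = 8.2e-05), and 5 did not pass. Goblet genes gave 0 and 8 adjusted over the list alone (list adjusted p = 0.011, adjusted p = 0.3 with an estimated correlation). Those not passed were both copies of itln1 and of otogl2 and tph1.L. Of these, otogl2.L remained abundant, at 12700, 4640 and 7160 CPM in induced and 17700, 22100 and 14400 CPM in control libraries. For itln1.L the values were 1340, 548 and 1320 CPM in induced and 2510, 3890 and 4330 CPM in control libraries. Induced library a held more ionocyte (1.37 ± 0.19, log2) and ciliated cell transcripts (0.80 ± 0.13) than its sister libraries.

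Wnt and BMP targets went in opposite directions at stage 17 as well. Of 46 Wnt targets 22 rose, such as tcf7.S (5.46 ± 0.27, adjusted p = 2.4e-09), the phosphatase gene dusp6.L fell and 23 did not pass. Wnt targets gave 23 and 1 adjusted over the list alone (list adjusted p = 2.8e-06, adjusted p = 0.097 with an estimated correlation). Of 43 BMP targets smad6.2.L and both copies of msx1 rose, 27 fell and 13 did not pass. BMP targets gave 3 and 28 adjusted over the list alone (list adjusted p = 1e-06, adjusted p = 0.078 with an estimated correlation). The ligand gene bmp4.S (−4.80 ± 0.36, adjusted p = 7.8e-08) and bambi.L (−2.93 ± 0.28, adjusted p = 8.8e-07) were among those that fell. Of 29 Hox genes 16 rose, 3 fell, among them hoxa3.L, and 10 did not pass. Hox genes gave 16 and 3 adjusted over the list alone (list adjusted p = 0.0013, adjusted p = 0.39 with an estimated correlation). Of 49 neural plate genes 20 rose, among them the tubulin gene tubb2b.L (3.61), 7 fell and 22 did not pass. Neural genes gave 21 and 7 adjusted over the list alone (list adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation). This list adjusted p was 0.053 without induced library c and 0.06 with library totals. Induced library c held more mesodermal (1.21 ± 0.21, log2), Hox (1.61 ± 0.32) and neural plate transcripts (0.64 ± 0.12) than its sister libraries.

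Several pluripotency genes were lower in induced caps at stage 17 than in epidermis of the same age. The Oct4 homologue pou5f3.1.L (−2.18 ± 0.38, adjusted p = 0.00022), the SoxB1 factor sox3.S (−1.79 ± 0.40, adjusted p = 0.0018) and klf2.S (−5.57) fell, and klf17.L rose (2.24). The other copy, pou5f3.1.S, differed less, at 24.1, 30.6 and 17.9 CPM in induced and 32.1, 30.8 and 38.3 CPM in control libraries. Of 46 pluripotency regulators 9 rose, 18 fell and 19 did not pass. Pluripotency regulators gave 11 and 18 adjusted over the list alone (list adjusted p = 0.15).

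The responses of stages 13 and 17 were largely shared. Both stages called 3408 genes higher, where 1030 were expected had the stages been independent and 90 went the opposite way. Both called 3693 genes lower (1190 expected, 55 opposite). Log2 fold changes across genes had a Pearson correlation of 0.742 and a Spearman correlation of 0.726. Stage 9 shared 46 higher genes with stage 13 (16.1 expected, 10 opposite) and 30 with stage 17 (18.8 expected, 13 opposite). Of lower genes it shared 8 and 9 (3.42 and 3.65 expected, 4 opposite each). Pearson correlations were 0.126 and 0.0368, and Spearman correlations 0.067 and 0.00368.

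Border and crest genes gained induction effect between stages 9 and 13. Over this interval the effect rose in 2175 genes and fell in 3108 (41.2% of calls rose, or 50.8% with library totals). Of 25 border genes 20 rose, 0 fell and 5 did not pass. Border genes gave 21 and 0 adjusted over the list alone (list adjusted p = 6.5e-22). Of 49 crest genes 27 rose, ets1.L and sema3f.L fell and 20 did not pass. Crest genes gave 31 and 2 adjusted over the list alone (list adjusted p = 1.2e-16). Of 14 shared regulators 9 rose, ets1.L fell and 4 did not pass. Shared regulators gave 9 and 1 adjusted over the list alone (list adjusted p = 2.5e-06). The genes tfap2a.L and id3.L, lowered at stage 9, gained 2.48 and 4.05 on the log2 scale.

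From stage 13 to 17 crest genes gained further while border genes lost. The effect rose in 987 genes and fell in 997 (1503 and 1431 blocked), with 49.7% of calls rising, or 64% with library totals. Higher genes numbered 630, 634 and 653 without control library a, control library b or induced library c of stage 17. Lower genes numbered 627 without that control library b. Of 49 crest genes 10 rose, snai1.L and snai2.S fell and 37 did not pass. Crest genes gave 13 and 4 adjusted over the list alone (list adjusted p = 1.4e-06, adjusted p = 0.07 with an estimated correlation). The effect on pdgfra.L rose by 7.22 ± 0.56 (adjusted p = 7.2e-06), that on ets1.S turned from lower to higher (4.80), and that on snai1.L fell by 5.17 on the log2 scale. Of 25 border genes 0 rose, 7 fell and 18 did not pass. Border genes gave 0 and 8 adjusted over the list alone (list adjusted p = 9e-10, adjusted p = 0.07 with an estimated correlation).

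Set against the blastula, pluripotency factors went different ways in induced caps. The Oct4 homologue pou5f3.3.L stood at 656 ± 136 CPM in the blastula and at 0.94 ± 0.376 CPM in induced caps of stage 13 (−9.45 ± 0.36, adjusted p = 1.3e-11). At stage 17 it stood at 0.186 CPM (−11.73, adjusted p = 7.9e-12), and control caps fell alike (−9.63 and −11.50). Its paralogue pou5f3.2.L went from 749 ± 118 CPM to 33.2 ± 31.7 and 0.302 CPM in induced caps (−4.50 and −11.24), against −2.50 and −8.70 in control caps. The SoxB1 factor sox3.S changed from 552 ± 85.2 CPM by −3.61 and −6.48 in induced and by −4.91 and −4.68 in control caps. In induced caps of stage 13 sox3.S stood at 28.6, 23.4 and 83.2 CPM in libraries a, b and c, so library c raised that value. Its relative sox2.L did not pass in induced caps of stage 13 (0.66 ± 0.65, adjusted p = 0.37), at 24.5 ± 17.9 against 15.5 ± 1.91 CPM in the blastula. It was lower in induced caps of stage 17 (−2.58 ± 0.70, adjusted p = 0.0036) and changed by −0.87 (adjusted p = 0.25) and −2.76 in control caps. In contrast, pou5f3.1.L rose at stage 13, from 66.7 ± 21.6 to 598 ± 322 CPM in induced (3.16 ± 0.39, adjusted p = 2.5e-06) and 1290 ± 124 CPM in control caps (4.28). Of 46 pluripotency regulators 16 rose, 17 fell and 13 did not pass in induced caps of stage 13. Pluripotency regulators gave 16 and 17 adjusted over the list alone (list adjusted p = 0.79), and their mean and median differed in sign. At stage 17, 11 rose, 24 fell and 11 did not pass. Pluripotency regulators gave 11 and 24 adjusted over the list alone there (list adjusted p = 0.018, adjusted p = 0.24 with an estimated correlation). In control caps 19 rose, 17 fell and 10 did not pass at stage 13 (19 and 17 adjusted over the list alone, list adjusted p = 0.76, mean and median again of different sign). In those of stage 17, 12 rose, 23 fell and 11 did not pass (12 and 23 adjusted over the list alone, list adjusted p = 0.056). That list adjusted p was 0.032 without control library a of stage 9.

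Regulators shared by blastula and crest were instead higher in induced caps than in the blastula. The snail factor snai1.L rose from 1.78 CPM by 7.51 ± 0.36 (adjusted p = 1.1e-10) at stage 13 and 6.86 ± 0.35 (adjusted p = 1.8e-10) at stage 17. The growth regulator myc.L rose from 6.53 ± 0.768 CPM by 5.38 ± 0.28 (adjusted p = 2e-10) and 5.55. Further rises were those of foxd3.L (6.09 and 8.98), id3.L (2.25 and 1.98) and tfap2a.L (1.90 and 1.35). Of 14 shared regulators 10 rose, both copies of ets1 fell and 2 did not pass at stage 13. Shared regulators gave 10 and 2 adjusted over the list alone (list adjusted p = 0.003, adjusted p = 0.074 with an estimated correlation). At stage 17 all 14 rose and 0 fell (14 and 0 adjusted over the list alone, list adjusted p = 2.8e-05), although ets1.L did not pass with library totals (0.11, adjusted p = 0.62).

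Control caps raised some of these regulators too. In them myc.L rose by 3.66 and 3.44 and id3.L by 1.96 and 1.44 (0.71 at stage 17 with library totals, adjusted p = 0.12). The crest factor foxd3.L fell (−2.81 at stage 13, at least 13.7-fold lower at stage 17). Of the 14, control caps raised 8 and lowered both copies of foxd3 at stage 13, and 4 did not pass (8 and 2 adjusted over the list alone, list adjusted p = 0.4). They raised 10 and lowered foxd3.L, foxd3.S and ets1.S at stage 17, and 1 did not pass (11 and 3 adjusted over the list alone, list adjusted p = 0.18).

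**Figure D5:**
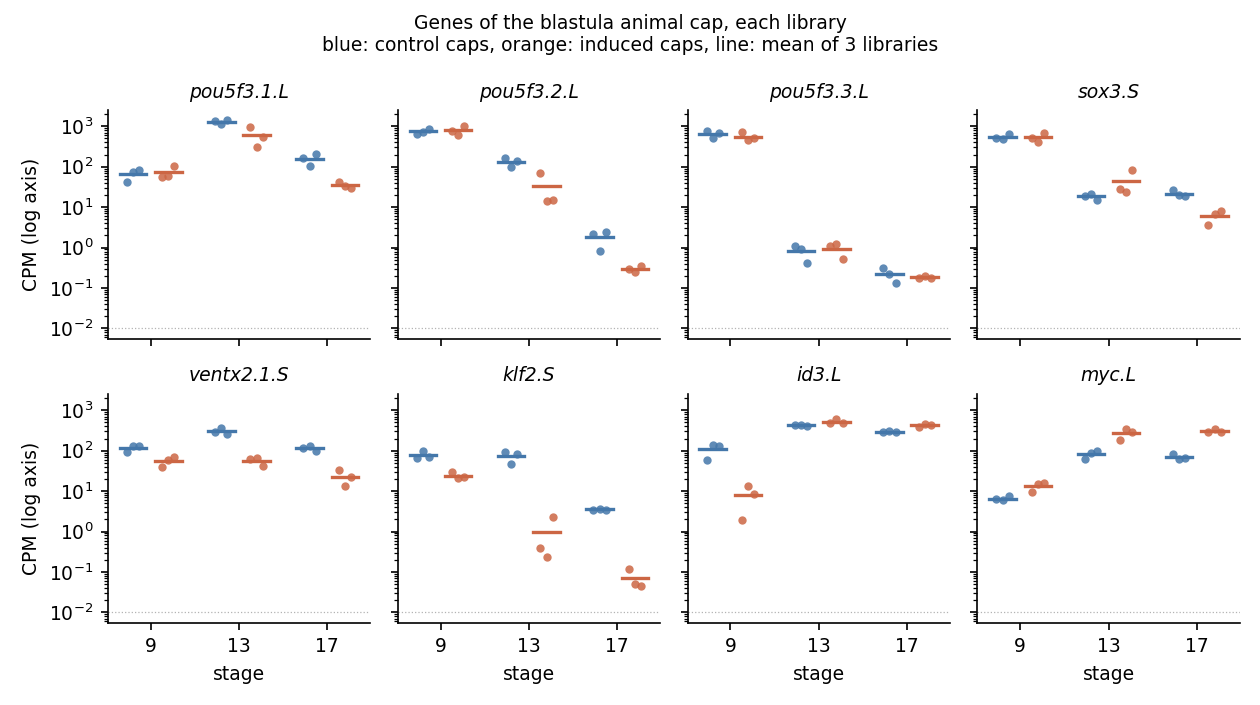
CPM (log axis) of 8 genes of the blastula animal cap against stage, each point a library, blue control caps and orange induced caps, lines the means of 3 libraries. Values below 0.01 are drawn at 0.01 (dotted line); pou5f3.2.L, pou5f3.3.L and sox3.S declined in both kinds of caps, while myc.L was higher in induced caps at stages 13 and 17.

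Induced caps gained crest, border and epidermal genes over the blastula. The crest factors sox10.S and twist1.S, a bHLH factor gene, were at least 8170-fold and 4740-fold higher at stage 17. At stage 13, 39 of 49 crest genes rose, ets1.L, ets1.S, rhob.L, ltk.S and dct.L fell and 5 did not pass. Crest genes gave 39 and 5 adjusted over the list alone (list adjusted p = 3.1e-08). At stage 17, 43 rose, rhob.L, ltk.S and dct.L fell and 3 did not pass (43 and 3 adjusted over the list alone, list adjusted p = 2.2e-11). Of 25 border genes 24 rose, 0 fell and hes1.L did not pass at stage 13. Border genes gave 24 and 0 adjusted over the list alone (list adjusted p = 9.7e-09). At stage 17, 17 rose, hes1.L, hes4.S, prdm1.L, prdm1.S and zic2.S fell and 3 did not pass. Border genes gave 18 and 5 adjusted over the list alone (list adjusted p = 0.0024, adjusted p = 0.24 with an estimated correlation).

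Epidermal genes rose over the blastula even in induced caps. The keratin gene krt70.L, for example, went from 3.43 CPM to 847 and 3100 CPM (7.95 and 9.82). Of 51 epidermal genes 45 rose, krt19.L and cldn6.1.L fell and 4 did not pass at stage 13. Epidermal genes gave 45 and 2 adjusted over the list alone (list adjusted p = 1.5e-09). At stage 17, 44 rose, krt19.L, bmp4.S and both copies of cldn6.1 fell and 3 did not pass (44 and 4 adjusted over the list alone, list adjusted p = 1.2e-08). In all, 8771 genes were higher and 8668 lower in induced caps of stage 13, and 9134 and 8776 in those of stage 17. With library totals the splits were 6301 and 11701, and 7258 and 10992.

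Control caps gained epidermal transcripts over the blastula. The intelectin gene itln1.L of mucus cells was at least 19600-fold higher at stage 13 (841 ± 257 CPM) and at least 85400-fold at stage 17 (3580 ± 950 CPM). The mucin-like gene otogl2.L rose by 16.03 and 17.24 to 7800 ± 884 and 18100 ± 3890 CPM. Blastula genes were lost. The nodal antagonist gene dand5.S of the egg changed by −9.86 at stage 13 and was 15800-fold lower at stage 17 (interval 2830 to 623000). The forkhead gene foxd4l1.1.L was at least 1010-fold lower at stage 17. In all, 8870 genes were higher and 8607 lower at stage 13, and 9210 and 8925 at stage 17. With library totals the splits were 6186 and 12086, and 6767 and 12008.

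Lists of epidermal cell types rose in control caps, although those of specialised cells lost the call with an estimated correlation. Of 51 epidermal genes 45 rose, both copies of cldn6.1 fell and 4 did not pass at stage 13 (45 and 2 adjusted over the list alone, list adjusted p = 1.1e-11). At stage 17, 44 rose, cldn6.1.L and krt18.1.S fell and 5 did not pass (44 and 2 adjusted over the list alone, list adjusted p = 1.8e-10). Of 36 multiciliated cell genes 33 rose, gmnc.S fell and 2 did not pass at stage 13. Multiciliated genes gave 33 and 1 adjusted over the list alone (list adjusted p = 5e-07, adjusted p = 0.47 with an estimated correlation). At stage 17, 32 rose, both copies of gmnc fell and 2 did not pass. Multiciliated genes gave 32 and 2 adjusted over the list alone (list adjusted p = 1.3e-06, adjusted p = 0.38 with an estimated correlation). Of 13 goblet and secretory genes 12 rose, 0 fell and tph1.L did not pass at each stage. Goblet genes gave 12 and 0 adjusted over the list alone at each (list adjusted p = 2.1e-05 and 2.2e-05, adjusted p = 0.16 and 0.16 with an estimated correlation). Of 22 ionocyte genes 13 rose, atp6v1a.S fell and 8 did not pass at stage 13. Ionocyte genes gave 13 and 1 adjusted over the list alone (list adjusted p = 0.013, adjusted p = 0.64 with an estimated correlation). At stage 17, 21 rose, 0 fell and atp6v1a.L did not pass. Ionocyte genes gave 21 and 0 adjusted over the list alone (list adjusted p = 3.1e-05, adjusted p = 0.3 with an estimated correlation). Of 43 BMP targets 36 rose, nbl1.L fell and 6 did not pass at stage 13. BMP targets gave 36 and 1 adjusted over the list alone (list adjusted p = 3.1e-09, adjusted p = 0.081 with an estimated correlation). At stage 17, 33 rose, nbl1.L, ventx1.2.S and ventx2.2.S fell and 7 did not pass. BMP targets gave 33 and 3 adjusted over the list alone (list adjusted p = 1.6e-06, adjusted p = 0.16 with an estimated correlation).

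More epidermal genes were lower than higher in induced than control caps of stage 13, and more blastula genes were higher than lower. This was tested with gene sets taken from control caps of another stage. Of 4844 genes that control caps had lost by stage 17, 995 were higher and 277 lower in induced than control caps of stage 13, and 3572 did not pass. The set was thus 20.5% higher and 5.72% lower, against 22% and 17.1% of the 13864 genes in neither this set nor the epidermal one. Because the set was chosen as genes lost by control caps, members already near 0 there could hardly be called lower. An example was dand5.S, at 0.343, 0.0788 and 0.542 CPM in control caps of stage 13. How many such genes either blastula set held was not counted. Camera gave an unadjusted p of 0.00015 with the preset and 0.079 with an estimated correlation, so the result rests on the preset correlation. Of 5791 genes that epidermis had gained, 602 were higher and 2594 lower (camera p of 6.3e-13, or 0.02 with an estimated correlation). At stage 17 the sets came from control caps of stage 13. Of 4711 blastula genes 1100 were higher (23.3%, against 25.3% of the 14562 genes in neither set) and 728 lower (15.5% against 18.7%; camera p of 0.066, or 0.24 with an estimated correlation). This p was 0.041 with a set threshold of 1 and 0.048 without induced library a of stage 17. Of 5226 epidermal genes 643 were higher and 2134 lower (camera p of 4.1e-09, or 0.039 with an estimated correlation).

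Lamprey caps of stage 11 gave a level for each gene model of an untreated blastula. Of 19781 models 16370 were detected, 10785 at 1 CPM or more and 6798 at 10 CPM or more, in libraries of 25857889, 24893104 and 29189490 gene counts. Levels were close between the 3 libraries (Spearman correlations 0.969 to 0.973), with a median coefficient of variation of 22.1%, or 14.7% without library 3. The most abundant model, PMZ_0059089-RA, stood at 15000 ± 1640 CPM and the next, PMZ_0050249-RA, at 11000 ± 1400 CPM; the models carry no gene names in the sources used here, so lamprey pluripotency and crest genes were not analysed here.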

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

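Splits of the libraries into other groups were planned before the data were examined, and the genes of the interactions were chosen by rule; all tests on hbg1.L, and the count of splits by what they keep, were chosen after the result was seen.

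Named genes of the interactions were picked by fitted size, and neither the sizes nor their order are bounds where a group holds few counts. From stage 9 to 13 the induction effect rose in 2175 genes and fell in 3108. Fitted gains were high for the receptor gene pdgfra.S (13.72 ± 1.51, adjusted p = 7.6e-05), the border factor pax3.L (13.52 ± 1.83, adjusted p = 0.00016), the Hox gene hoxb2.S (13.39 ± 3.13, adjusted p = 0.0091), the aquaporin gene aqp3.L (13.17 ± 1.51, adjusted p = 4.7e-05) and the homeobox gene nkx1-2.L (13.17 ± 3.04, adjusted p = 0.012). Control caps of stage 13 held no counts of pdgfra.S, pax3.L, hoxb2.S and nkx1-2.L and 1 of aqp3.L, so these values depend on the fit to empty or nearly empty groups. The calls of hoxb2.S and nkx1-2.L were lost without control library c of stage 9 (adjusted p = 1 for each). Fitted losses, where hbg1.L, neurl1.L and iqca1.L had no counts in control caps of stage 9, included hbg1.L (−10.01 ± 1.64, adjusted p = 0.00065), neurl1.L (−8.25 ± 2.48, adjusted p = 0.029), stmnd1.L (−7.92 ± 1.55, adjusted p = 0.0017) and iqca1.L (−7.40 ± 2.34, adjusted p = 0.036; 0.055 blocked). The call of iqca1.L was lost without control libraries a, b or c of stage 9 (0.063, 0.057 and 0.058), control libraries b or c of stage 13 (0.057 and 0.055), induced libraries b or c of stage 9 (0.13 each) or induced library b of stage 13 (0.057). The gene neurl1.L lost its call without control library a (0.053) or induced libraries b (0.1) or c (0.11) of stage 9.

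From stage 13 to 17 the effect rose in 987 genes and fell in 997. Fitted gains included the metalloprotease genes astl2d.2.L (8.25 ± 1.92, adjusted p = 0.018; without control libraries a or c of stage 13, 0.061 and 0.11) and astl2d.3.L (8.1 ± 1.84, adjusted p = 0.016; without control library a, 0.085), the receptor gene npr3.L (8.12 ± 1.62, adjusted p = 0.0059), the immune checkpoint gene vsir.S (7.34 ± 1.72, adjusted p = 0.018; without control library a of stage 13, 1) and pdgfra.L (7.22 ± 0.56, adjusted p = 7.2e-06), whose effect grew from 2.2 to 9.41. Fitted losses included ltbp1.L, a latent TGF-beta binding protein gene (−9.34 ± 1.52, adjusted p = 0.0022), the neural homeobox gene irx3.L (−9.11 ± 1.41, adjusted p = 0.0011), the opsin genes tmtops.L (−8.77 ± 1.87, adjusted p = 0.014) and val.L (−8.61 ± 1.97, adjusted p = 0.014), and the neurotrophin gene ngf.S (−8.74 ± 1.03, adjusted p = 0.00014), which went from 2.30 to −6.44. A group with no counts entered the values of ltbp1.L, vsir.S and tmtops.L, and 1 with a single count those of npr3.L and irx3.L. Both tmtops.L and val.L lost this call without induced library c of stage 13 (adjusted p = 1 and 0.58), which held more ciliated cell and ionocyte transcripts than its sister libraries, so their change rests on that library.

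For pairwise comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At stage 13 the real split called 9877 genes and the highest other 0 (1 of 10 as large), at stage 17 11013 and 0 (1 of 10). Against the blastula the real splits called 17439 and 17910 genes for induced caps of stages 13 and 17 and 17477 and 18135 for control caps, with 0 in the highest other each time (1 of 10 each). At stage 9, 3 of 10 splits were as large: the real split called 101 genes and the highest other 369, several times the real count, which points to a structure of the samples. Splits that part all 3 same-letter pairs, as the real split does, numbered 4, and the highest of the others called 0 genes; the blocked model called 101 higher and 20 lower.

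For the interactions, groups within each stage were redrawn 100 times. From stage 9 to 13, 7 of 100 draws called as many genes as the real 5283 (highest other 7899; 5720 among the 18 that part as many pairs), and from stage 13 to 17, 8 of 100 called as many as the real 1984 (highest other 6951; 6267 among the 18), so that chance was not excluded by this count. The other draws as large all kept the real grouping of 1 of the stages: of 84 that kept neither, the highest called 1 gene. The 9 draws that kept stage 13 and broke stage 9 called 5198 to 7899 genes, 6 of them as many as the real one, since an effect set against a mixed pair of groups changes as well. The 9 that kept stage 17 and broke stage 13 called 871 to 6951. The 6 that kept stage 13 and broke stage 17 called 196 to 2167.

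hbg1.L, a haemoglobin gene, was counted 3256 times in induced caps of stage 9 and never in control caps of that stage (at least 1070-fold higher), with 12 counts over the later control libraries. A candidate explanation is globin sequence attached to the injected wnt8a transcript: its counts per 100 wnt8a.L counts were 8.21, 6.2 and 7.94 in the 3 libraries, a spread of 1.32 times. The ratio to chrd.1.S spread 2.97 times there, which argues against globin sequence on the chordin transcript at that stage. Globin genes raised by the induction remain open, since 0 other globin genes rose in edgeR's test at stage 9 (hba-l5.L 0.23 ± 0.47, hbz.L 0.22 ± 0.47) but a single one could rise alone. At stages 13 and 17, with 7 to 27 hbg1.L counts, the ratios per 100 wnt8a.L counts were 5.28, 2.14 and 0.873, and 9.66, 10.4 and 1.66, but those per 100 chrd.1.S counts were closer, 0.114, 0.119 and 0.091, and 0.546, 0.513 and 0.176, so the source is not settled.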

How the results depend on the processing

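Leaving out the libraries rich in mesodermal or in ciliated cell transcripts was chosen after the results were seen; the other alternatives were planned. In all 44 results and 18 kinds of alternative were computed, and the cause of a difference was not tested unless stated.

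The stage 9 comparison depended most on the method. Of genes higher, 85 by the settings used, DESeq2's Wald test called 156, a fit of the stage 9 libraries alone 10, the block with these libraries alone 387, an adjusted p of 0.01 40, and leaving out single libraries 41 to 158. Of genes lower, 16 by the settings used, these gave 32, 0, 242, 8 and 7 to 26. The 0 is from edgeR's quasi-likelihood test, against 32 by DESeq2. In the fit of all libraries without the block 815 of 24499 genes had an unadjusted p under 0.05, fewer than chance alone would give. That fit left spread shared by letter in the error, so the number does not show that further changes are absent. With the stage 9 libraries alone, genes such as nog.L (adjusted p = 0.46) and id3.L (0.31) were not called, while their fold changes were 4.47 and −3.81.

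The responses of stages 13 and 17 were less sensitive. A 2-fold minimum left 2711 genes higher at stage 13, 3384 at stage 17 and 1787 higher at both. Without induced library b of stage 13 and induced library c of stage 17, rich in mesodermal transcripts, 3670 genes were higher and 4352 lower at stage 13 and 4560 and 4550 at stage 17; without induced libraries c of stage 13 and a of stage 17, rich in ciliated cell and ionocyte transcripts, 4253 and 4664, and 5412 and 5067.

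Of the interactions, that from stage 9 to 13 kept 1196 genes higher and 1910 lower at an adjusted p of 0.01. That from stage 13 to 17 varied more: of 987 higher, 1503 when blocked, 2316 blocked with the compared groups alone, 323 at an adjusted p of 0.01, 456 without the libraries rich in mesodermal transcripts and 630 to 1175 without single libraries. Of 997 lower, DESeq2 called 1576, the block with the compared groups alone 1610, an adjusted p of 0.01 417, the fit without the mesoderm-rich libraries 576, and leaving out single libraries gave 627 to 884.

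List tests depended on the correlation assumed. With an estimated correlation, lists higher numbered 1 instead of 4 at stage 9, 3 instead of 7 at stage 13 and 2 instead of 7 at stage 17, and lists lower 0 instead of 5 at stages 13 and 17. Against the blastula, lists higher numbered 3 instead of 11 and 3 instead of 9 for induced caps of stages 13 and 17 (lower 0 instead of 1, and 1 instead of 2), and 1 instead of 5 and 1 instead of 6 for control caps (lower at stage 13 0 instead of 1). At stage 9 the 4 lists higher became 2 when blocked, 1 with copies summed and 1 to 3 without single libraries, and the 3 lists lower 2 to 5. For control caps of stage 13 against the blastula 8 lists were higher with library totals, and at stage 17 lists lower numbered 1 to 2 without single libraries. Without the mesoderm-rich libraries the placode list passed at stage 13 (list adjusted p = 0.027) and the neural plate list of stage 17 did not (0.052).

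The blastula set of stage 13 had a p of 0.079 with an estimated correlation; at stage 17 the p was 0.041 with a set threshold of 1 and 0.048 to 0.1 without single libraries. Of 750 pairs of named gene and comparison, 11752 alternative values were computed: 11345 gave the same call, 229 lost it, 177 gained it and 1 reversed, tfap2a.L in control caps of stage 17 against the blastula (0.72, or −0.03 with library totals, adjusted p = 0.92). The block changed 22 calls of named genes and the mesoderm and Hox list calls of stage 9, and no other list call. Lamprey models detected numbered 10785 at 1 CPM or more, and their median coefficient of variation was 14.7 to 20.9% without single libraries. The planned matching of lamprey models to symbols was not run.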

Other observations

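All tests of mesodermal transcripts in single libraries and the threshold of 100 actc1 counts were chosen after the result was seen. So were the test of a general delay and the shares of genes in neither set. The other tests of the blastula set were planned. In the test against genes in neither set, asking for the estimated correlation as well was decided after the first p was seen.

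Gland genes were higher in induced than control caps at stage 17. The cement gland gene ag1.L was higher by 2.69 ± 0.34 (adjusted p = 1.2e-05), at 230 ± 56.3 against 35.7 ± 13.8 CPM. At stage 13 it stood at 474 ± 154 CPM in induced and 268 ± 101 CPM in control caps, so its mean was lower at stage 17 in both, by the larger ratio in control caps. Also at stage 17, the hatching gland metalloprotease gene astl2f.S was at least 2180-fold higher (126 ± 123 CPM, uneven between libraries). All 3 gland genes measured rose at stage 17 (0 fell, 3 and 0 adjusted over the list alone, list adjusted p = 0.0099, adjusted p = 0.057 with an estimated correlation), after astl2f.S at stage 13, where ag1.L (0.82, adjusted p = 0.05; 0.034 blocked) and ag1.S (0.035 blocked) did not pass (2 and 0 adjusted over the list alone, list adjusted p = 0.13); at stage 9 none passed (list adjusted p = 0.18). Placodal genes split: of 23, 8 rose and eya2.S and both copies of tbx2 and isl1 fell at stage 13 (10 not passed, 8 and 5 adjusted over the list alone, list adjusted p = 0.14; 0.042 without induced library b), and 7 rose and 7 fell at stage 17 (9 not passed, 7 and 7 adjusted over the list alone, list adjusted p = 0.46).

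Mesodermal and endodermal genes went both ways at stage 17, and neither list passed. The heart and branchial factors hand2.S (−6.16 ± 0.57, adjusted p = 5.9e-07) and nkx2-5.S (−6.58) fell, within a mesodermal list of which 14 of 43 rose, 8 fell and 21 did not pass (15 and 8 adjusted over the list alone, list adjusted p = 0.51). Of 23 endodermal genes 7 fell and 4 rose at stage 13 (among them foxa4.L and cer1.S; 12 not passed, 4 and 7 adjusted over the list alone, list adjusted p = 0.84, its mean above 0 and its test below), and 9 fell and 3 rose at stage 17 (among them gata6.L and cer1.S; 11 not passed, 3 and 9 adjusted over the list alone, list adjusted p = 0.19).

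The list of maternal transcripts did not pass between induced and control caps at any stage. Most of its genes fell against the blastula in both kinds of caps. Of 62, 11 rose and zar2.L, zar2.S, rps6ka3.L and sybu.S fell at stage 13 (47 not passed, 10 and 4 adjusted over the list alone, list adjusted p = 0.31). At stage 17, 14 rose and 7 fell (41 not passed, 10 and 6 adjusted over the list alone, list adjusted p = 0.67, its median below 0 and its mean above). Over all genes 40.3% and 45% were called at stages 13 and 17. Members nearly absent from both kinds of caps by then, such as ccnb1.S, could hardly differ, and how many there were was not counted. Of all 24499 genes 815 had an unadjusted p under 0.05 at stage 9, fewer than chance alone would give, and DESeq2 called 156 and 32. The 815 come from the fit without the block, which left spread shared by letter in the error. Of the maternal transcripts edgeR's test passed none at that stage (list adjusted p = 0.32). Against the blastula 44 and 43 fell in induced caps of stages 13 and 17 (11 and 8 rose, list adjusted p = 7.1e-05 and 1.2e-08, adjusted p = 0.076 and 0.022 with an estimated correlation) and 44 and 50 in control caps (list adjusted p = 4.1e-06 and 1.2e-09, adjusted p = 0.081 and 0.024 with an estimated correlation), among them the cyclin gene ccnb1.S (−9.34 and −11.67 in induced, −9.47 and −12.59 in control caps). Reference genes were not all stable: of 38, none passed at stage 9 (1 and 0 adjusted over the list alone, list adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation; 0.17, 0.24 and 0.75 without control libraries a, c or induced library b), 8 rose and both copies of actg1 fell at stage 13 (28 not passed, 6 and 2 adjusted over the list alone, list adjusted p = 0.096; 0.048 without induced library c), and 12 rose and 6 fell at stage 17 (20 not passed, 12 and 6 adjusted over the list alone, list adjusted p = 0.12). The replication regulator gmnn.S rose by 2.79 at stage 13, and cytoskeletal actg1.L (−1.23) and actg1.S (−1.27) were lower.

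A pair of induced libraries carried muscle transcripts: actc1, a muscle actin gene, had 673 counts in library b of stage 13 and 442 in library c of stage 17, and at most 28 in any other. Whole embryo or vegetal tissue mixed in would raise endodermal genes as well, and these rose by at most 0.33 on the log2 scale, against 1.12 ± 0.30 and 1.21 ± 0.21 for mesodermal genes; but 12 and 15 of 23 were higher, many near 0 counts, and the endodermal sox17b.1.L had 28 counts in library b of stage 13 against 4 and 3, and 6 in library c of stage 17 against 0 and 2, so this stays open. Marginal zone tissue taken along at dissection could occur in either treatment and stays open: 2 of 9 induced and 0 of 9 control libraries exceeded 100 counts, and with 2 such libraries the exact Fisher p of 0.471 is the smallest that can arise, so it decides nothing. Mesoderm induced in the caps by the injected factors stays open too, as untested.

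More blastula genes were higher than lower in induced caps of stage 13, which may have several origins. Epidermal genes in the background of the test could produce this: against 13864 genes in neither set the p was 0.044, which met the bound written beforehand (under 0.05), but with an estimated correlation it was 0.33, so this explanation was left open. A general delay of the induced caps would leave few blastula genes lower. Of 1272 called, 277 or 21.8% were lower, which argues against delay as the whole cause. Of the whole set 5.72% were lower, against 17.1% of genes in neither set. A delay predicts that direction, but so does the choice of the set, since members near 0 in control caps can hardly be called lower. Of the set 20.5% were higher, against 22%, which a delay does not predict, so delay as part of the cause stays open. Loss of RNA of the outer epidermal layer in 1 ratio would move its genes alike. The middle 50% of the epidermal set spanned 2.71 on the log2 scale (−2.50 to 0.21), and 602 of its 5791 genes were higher. These values argue against a fall of the whole set in 1 ratio. The set holds genes that control caps had gained by stage 17, not those of the outer layer alone, so loss of that layer stays open. A retained blastula program in crest precursors stays open as well, with differences in cell composition untested.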
